A study of Caenorhabditis elegans with 4 samples.

How the data were processed

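Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on late embryos of Caenorhabditis elegans that carried a transgene for NFYA-1 fused to green fluorescent protein (GFP). Per the labels' protocols, worms were grown at 20 °C, crosslinked with 2% formaldehyde and sonicated, 10% of the lysate was kept as input DNA, and anti-GFP antibodies collected the tagged factor with the DNA bound to it. The series holds 4 samples, which are 2 ChIP libraries and 2 input libraries with matching replicate numbers. Read counts, signal tracks and values of the input libraries were not analysed here, so the sequencing depth of each library is unknown.

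The data analysed were 3 deposited peak lists, from ChIP replicate 1, ChIP replicate 2 and the combined data. Per the file headers and source column, the peaks were called with PeakSeq on the WormBase WS180 genome build. The only value the authors deposited per peak is a q-value, a p-value corrected for multiple testing, and each list is sorted by it. The aligner, the PeakSeq version, the threshold, the role of each input library and the way the combined list was made are not given in the sources used here. Peak strength is therefore the authors' −log10 q throughout. It depends on sequencing depth as well as on enrichment, and it was used to rank or filter peaks within a list. Where it was set side by side between lists, it was as values of overlapping intervals. Each shared replicate 1 peak was matched to the strongest replicate 2 peak that it overlapped. Each combined peak was matched to the strongest peak of each replicate that it overlapped. A peak could therefore enter more than 1 match.

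Lists were compared by overlap of at least 1 bp. Shares of peaks carry exact Clopper-Pearson 95% intervals, which cover counting error over peaks only. Replicate overlap was tested one-sided against 1000 circular shifts of the other list within each chromosome. Shared and unshared peaks were compared by the difference of median −log10 q, with a two-sided permutation test of 100000 resamples. Peaks per chromosome were tested against the share of the genome span with two-sided exact binomial tests and Benjamini-Hochberg adjustment over 6 chromosomes. The span of a chromosome ran from the first to the last peak over the 3 lists, because chromosome lengths of build WS180 were not used here. The density of peaks was also compared over full 1 Mb bins, with a permutation of bins between chromosomes, which was not planned. All these tests are across peaks or bins, which are not independent replicates. With 2 ChIP libraries, no test measured the spread between libraries, and nothing in the labels says whether the libraries came from separate cultures.

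The samples, the named-item rule and the tests of replicate overlap, of shared against unshared peaks and of peaks per chromosome, with X against the autosomes, were fixed before the data were examined. Chosen after the data were seen were the span in place of chromosome length, the ratio of III to the other autosomes, the 1 Mb bins and densest stretches, the subsets by rank or by presence in the replicates, apart from the stronger part of each list and its 1000 strongest peaks, the comparisons of the replicates by chromosome, those of chromosome I between lists, and the strong regions that the combined list lacks. The rule was to name the genes at the 20 strongest combined peaks found in both replicates, all genes of 3 gene lists, and the leading genes of other lists. The gene table at hand is for assembly WBcel235, a different build from the peak lists, so no peak was assigned to a gene and the 20 regions are named by position alone. For the same reason 5 planned results were not run: the share of peaks at promoters, the CCAAT motif at peak centres, the other motifs, the gene lists, and the loci carried by the transgene. Peaks per chromosome were also to be tested against each chromosome's share of protein-coding genes, and that part was not run. Alternatives covered the overlap rule, stricter thresholds and the use of each replicate list alone.

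The functions for overlap, density and strength were tested on simulated data in 20 runs of 3000 peaks per list. With 80% of peaks simulated as shared between the replicates, a mean of 80.7% was found, and 3.03% after circular shifts. A simulated density of 1.5 on chromosome III relative to the other autosomes came out as 1.49 and passed the exact test in 20 of 20 runs. The analysis used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.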

Results

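NFYA-1 is a subunit of NF-Y, a complex known for binding CCAAT boxes. Its binding across the genome was mapped in late C. elegans embryos by ChIP-seq of the GFP-tagged protein, in 2 replicates. The replicate 1 list held 2907 peaks that covered 1242 kb, and the replicate 2 list held 3319 peaks that covered 1306 kb. The combined list held 5320 peaks over 2265 kb. Median peak width was 353 bp in replicate 1, 331 bp in replicate 2 and 352.5 bp in the combined list. The largest q-value was 0.000232 in replicate 1, 0.000321 in replicate 2 and 0.000337 in the combined list.

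The strongest NFYA-1 regions of the combined list were found on all 6 chromosomes. Among the 20 combined peaks with the smallest q-values that were also found in both replicates, 4 lay on chromosome I, 4 on II, 2 on III, 3 on IV, 3 on V and 4 on X. They were 684 to 4109 bp wide, with a median of 1859.5 bp, against 352.5 bp for the whole list. In build WS180 the first was chromosome III from 1618209 to 1619804, with a combined q of 1.66e-233, 1.40e-197 in replicate 1 and 7.20e-203 in replicate 2. Next came chromosome I from 1834589 to 1837459, with a combined q of 8.66e-228. By combined q, the strongest of the 20 on chromosome IV ran from 8430355 to 8433246 (1.28e-212). That on II ran from 11748538 to 11750450 (1.71e-211) and that on X from 16611222 to 16613027 (1.10e-210). On I, II, III and IV, both replicates held a stronger region than any of these 20 on the same chromosome, which the combined list lacks (described below). On chromosome V the leading region by combined q ran from 9730702 to 9732240, with a combined q of 5.74e-191. Its q was 5.85e-134 in replicate 1 and 1.97e-106 in replicate 2. Both replicates were stronger on V from 6098618 to 6101481 (4.98e-154 and 1.26e-157). The widest of the 20 was on V as well, from 14685532 to 14689640. A second region on X, from 6090442 to 6093336, had a q of 2.00e-190 in replicate 1 and 6.01e-177 in replicate 2. These were smaller than those of the X region named first (3.56e-139 and 9.15e-108). What the annotation places at these positions was not analysed here. Wider peaks were also stronger over the whole combined list (Spearman's rho of 0.587 across peaks, which are not independent replicates).

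Most NFYA-1 peaks of either replicate were found in the other. Of the replicate 1 peaks, 2492 of 2907 overlapped a replicate 2 peak (85.7%, 95% interval 84.4 to 87.0). Of the replicate 2 peaks, 2490 of 3319 overlapped a replicate 1 peak (75.02%, 73.51 to 76.49). After circular shifts the shares were 2.93% ± 0.528 (SD over 1000 shifts) and 2.58% ± 0.462. The observed shares were 29.2 and 29.1 times these, and no shift reached them (one-sided permutation p = 0.001 for each, the smallest that 1000 shifts can give). The 1033 strongest peaks of replicate 1 and the 1157 strongest of replicate 2 were all matched. The first unmatched peak had a q of 2.22e-10 in replicate 1 and 7.05e-10 in replicate 2. In the weakest quartile, 59.1% of 727 replicate 1 peaks and 39.9% of 830 replicate 2 peaks were matched.

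Peaks that both replicates shared were stronger than those found in 1 replicate. In replicate 1 the median −log10 q was 8.16 for shared and 4.39 for unshared peaks, a difference of 3.77. In replicate 2 the medians were 8.62 and 4.48, a difference of 4.14. Both differences gave a two-sided permutation p of 1e-05 across peaks, the smallest that 100000 resamples can give. Each list holds only peaks that passed its threshold, and a peak near it in 1 list can miss it in the other. The direction could follow from that alone, so the test cannot say more. Shared peaks were also wider, with medians of 357 against 318 bp in replicate 1 and 358 against 267 bp in replicate 2. Over the 2492 matched pairs, −log10 q in the replicates had a Spearman's rho of 0.819 and a Pearson's r of 0.888 on the log scale, computed across peaks. The median log2 ratio of replicate 1 to replicate 2 was -0.01 (quartiles -0.33 and 0.30).

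**Figure D1:**
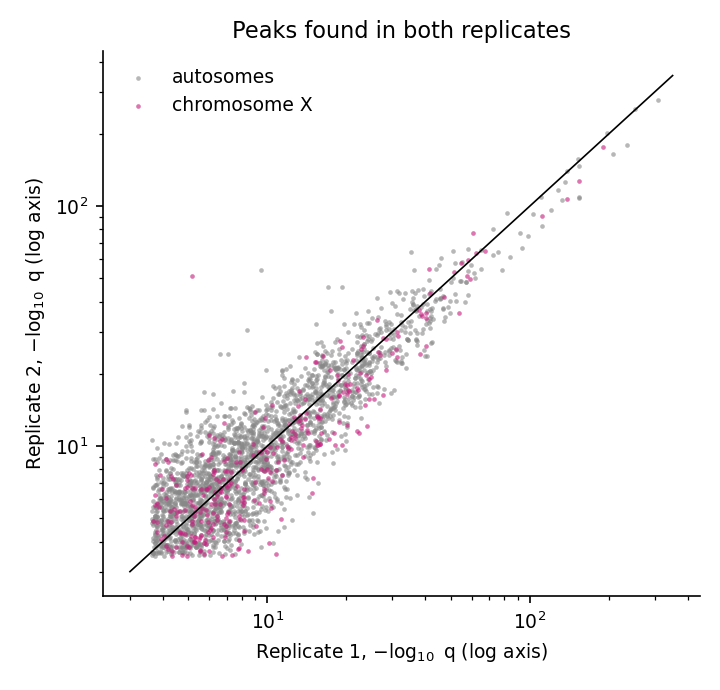
Strength of the 2492 matched peaks as −log10 q in replicate 1 (x axis) and replicate 2 (y axis), both on log axes. Each point is a matched pair, grey for autosomes and magenta for chromosome X, and the line marks equal values; the points follow the line, with 66.3% of X pairs on the replicate 1 side.

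The strong peaks of the combined list were found in both replicates, and most of its weakest peaks in neither. Of its 5320 peaks, 2469 overlapped peaks of both replicates (46.4%, 95% interval 45.1 to 47.8). A further 393 overlapped replicate 1 alone and 751 replicate 2 alone. The remaining 1707 (32.1%) overlapped no replicate peak. Median −log10 q was 16.5 for peaks in both, 6.77 for peaks in 1 replicate and 4.53 for peaks in none. Median width was 424, 315 and 283 bp in the same order. With the list split into 10 parts by rank, 100% of the strongest part and 0.188% of the weakest part were in both replicates. The file name alone says that this list combines the replicates, so its overlap with them is not independent evidence. Among the 2660 stronger peaks, 86.1% were in both replicates.

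**Figure D2:**
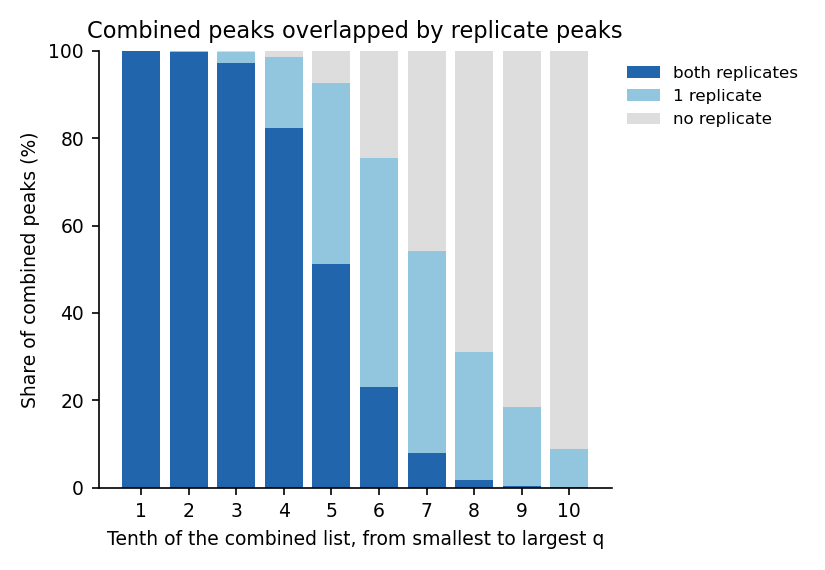
Share of combined peaks (y axis, percent) that overlap peaks of both replicates, 1 replicate or no replicate, in 10 parts of the list by rank (x axis, 532 peaks each, smallest q first). Peaks in both replicates make up 100% of the first part and peaks in none make up 91.2% of the last.

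NFYA-1 peaks were densest on chromosome III. It held 1136 of the 5320 combined peaks (21.4%, 95% interval 20.3 to 22.5) on 13.8% of the span, or 82.6 peaks per Mb. Chromosome I had 60.9 peaks per Mb, II had 56.3, IV had 49.0, V had 40.4 and X had 41.2. The density of III was 1.63 times that of the other autosomes together (exact interval 1.53 to 1.75, two-sided exact binomial p = 5.60e-43). The same ratio was 1.86 in replicate 1 and 1.87 in replicate 2. It was 1.89 for combined peaks in both replicates and 1.24 for those in none. Over 1 Mb bins, III had 82.7 ± 21.5 combined peaks (SD, 13 bins) against 50.8 ± 14.9 (67 bins) on the other autosomes, with a two-sided permutation p of 1e-05, the smallest possible. Of the 13 bins of III, 12 lay above the mean of the other autosomes.

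The densest stretch in each list was chromosome III from 12000001 to 13000000. It held 110 combined peaks, 89 replicate 1 peaks and 98 replicate 2 peaks, where the mean over all 97 bins was 53.2 ± 19.2, 29.0 ± 12.96 and 33.1 ± 14.9 (SD). Next was III from 4000001 to 5000000, with 109 combined, 73 replicate 1 and 75 replicate 2 peaks, tied in replicate 2 with III from 8000001 to 9000000. Of the 500 strongest combined peaks, 31 lay in the 12000001 to 13000000 stretch, and the second bin by this count held 15. Each of its 10 sections of 100 kb held between 6 and 19 combined peaks.

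Chromosomes V and X held a smaller share of the peaks than of the span in each list, and IV did by the exact test in the combined list. V held 15.8% of combined peaks on 20.9% of the span (exact binomial, adjusted p = 9.89e-21) and X held 13.4% on 17.4% (adjusted p = 7.37e-15). IV held 16.03% on 17.47% (adjusted p = 0.00688), but did not pass the same exact test in replicate 1 (adjusted p = 0.100) or replicate 2 (adjusted p = 0.0940). Because these shares are parts of a whole, the excess on III lowers the others. The autosomes other than III together had 50.6 combined peaks per Mb, against 49.0 on IV, 40.4 on V and 41.2 on X. The low share of IV therefore cannot be told apart from the excess on III. The density of X was 0.736 times that of the autosomes, III included (exact interval 0.680 to 0.797), 0.742 times in replicate 1 and 0.619 times in replicate 2. The permutation of 1 Mb bins gave a two-sided p of 0.0022 for X in the combined list. Among the 500 strongest combined peaks the ratio for X was 0.788 and did not pass the exact test (p = 0.067). In that subset X had 4.10 peaks per Mb, against 4.14 on I, II, IV and V together.

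**Figure D3:**
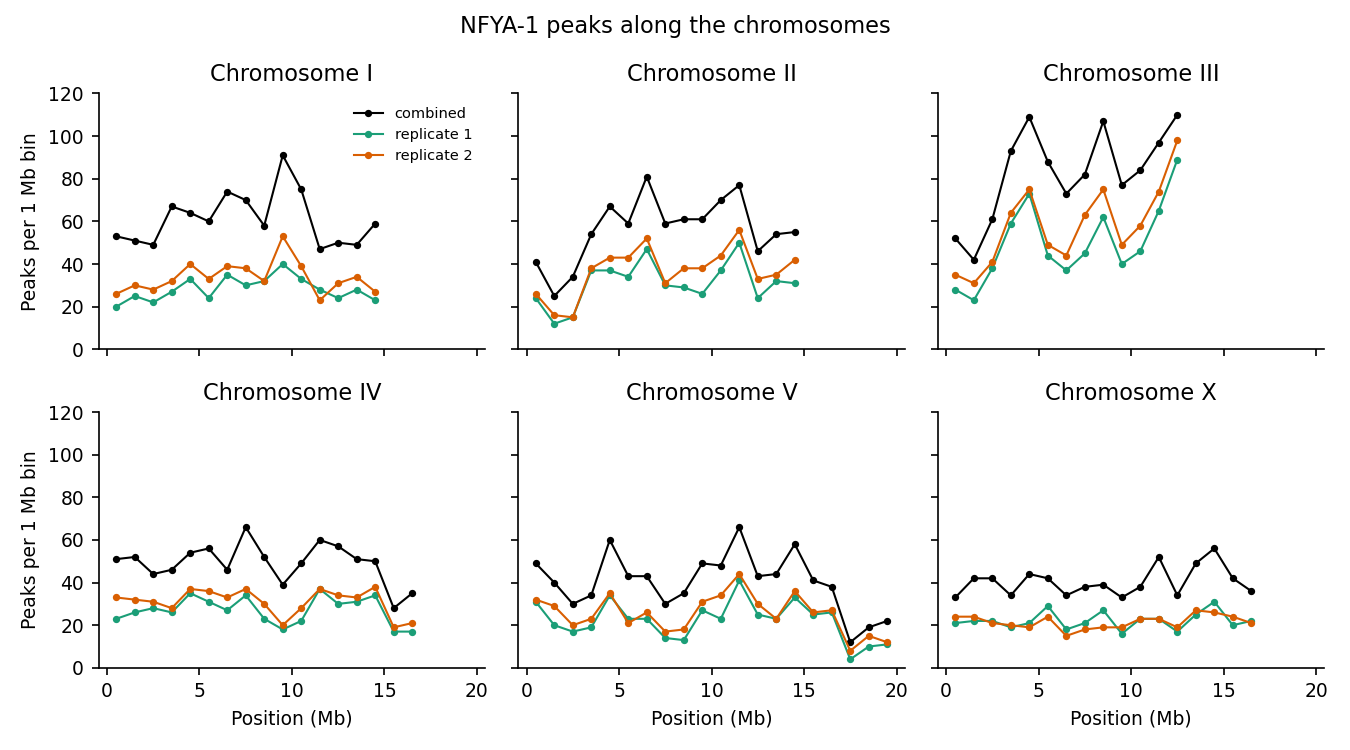
Peaks per full 1 Mb bin (y axis) along each chromosome (x axis, Mb, build WS180) in the combined list (black), replicate 1 (green) and replicate 2 (orange). Chromosome III reaches 110 combined peaks between 12 and 13 Mb, while X stays between 33 and 56.

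The replicates differed on chromosome X. Of the peaks found in replicate 1 alone, 83 of 415 lay on X (20.0%), against 73 of 829 found in replicate 2 alone (8.81%). The odds ratio was 2.59 (two-sided Fisher's exact test across peaks, adjusted p = 3.38e-07 over 6 chromosomes). For the other chromosomes the adjusted p was 0.0696 or more. At matched peaks on X, the median log2 ratio of replicate 1 to replicate 2 was 0.16 and 66.3% of 309 pairs were stronger in replicate 1. On the autosomes the median was -0.03 and 46.8% of 2183 pairs were stronger in replicate 1. Over all peaks of each list, the X share was 13.5% in replicate 1 and 11.5% in replicate 2, which did not pass after adjustment (Fisher's exact test, adjusted p = 0.113). These values compare 2 libraries.

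Chromosome I differed from chromosomes II to V in the combined list. On I, 40.8% of 917 combined peaks overlapped no replicate peak, against 29.1% on chromosomes II to V (odds ratio 1.68, two-sided Fisher's exact test across peaks, p = 2.12e-11). X had 36.3%. I held 17.2% of combined peaks, but 14.6% in replicate 1 and 15.2% in replicate 2, close to its 15.1% of the span. At peaks found in both replicates, the combined −log10 q divided by the sum of the replicate values had a median of 1.08 on I (quartiles 0.985 and 1.22, 377 peaks). It was 0.937 on II to V (0.848 and 1.04, 1785 peaks) and 0.983 on X. Over 1 Mb bins the median for I lay 0.151 above that of the other autosomes, with a two-sided permutation p of 1e-05, the smallest possible. Neither p-value for I was adjusted over chromosomes, and I was picked after the data were seen.

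**Figure D4:**
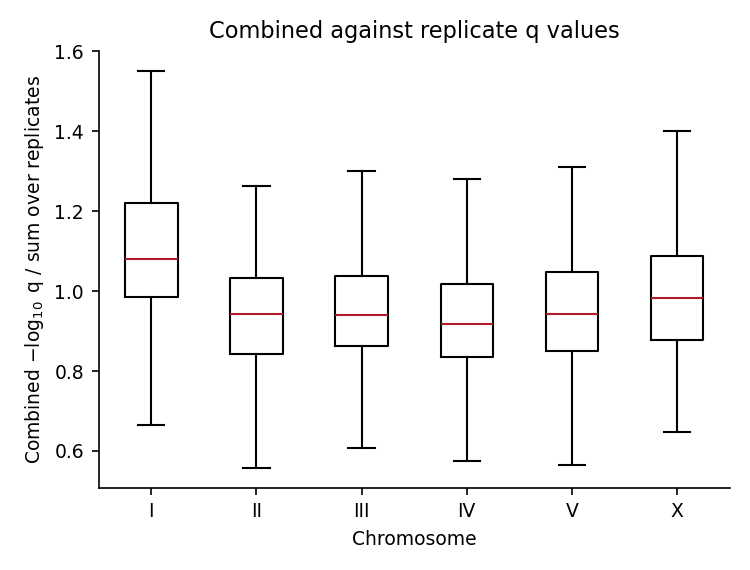
Combined −log10 q divided by the sum of both replicates' −log10 q (y axis) at combined peaks found in both replicates, by chromosome (x axis). Boxes span the quartiles, red lines are medians, whiskers reach the last value within 1.5 box lengths and points beyond are not drawn; the median is 1.08 on I and between 0.917 and 0.983 on the others.

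Some of the strongest replicate regions did not overlap any interval of the combined list used here. The strongest region of both replicates was on chromosome III, from 8416839 to 8418066 in replicate 1 (q of 6.57e-310) and from 8416818 to 8418100 in replicate 2 (2.13e-278). The second of both was on II, from 5660375 to 5662792 in replicate 1, with a q of 4.80e-252 and 3.99e-255. A region on IV from 14032444 to 14034938 had a q of 3.48e-236 and 6.85e-180. A region near the right end of the span of I, from 15063995 to 15067654, had a q of 5.34e-208 and 6.93e-165. These are ranks 1 to 4 in replicate 1 and ranks 1, 2, 4 and 6 in replicate 2. The only other shared peak with no combined interval in either replicate was weak, with a q of 2.72e-05 in replicate 1. The 20 strongest combined regions described above therefore leave out these 4.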

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

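The alternatives that left out chromosome I, used the 500 strongest peaks, peaks in both replicates or 1 Mb bins, or left out the densest bins of III were chosen after seeing the data. Of 29 alternative values for 10 results, 23 kept their direction and their side of the threshold or interval. The replicate overlap was 82.1 to 87.5% for replicate 1 and 71.9 to 76.6% for replicate 2 over the 50% reciprocal overlap, midpoints within 200 bp, the stronger peaks of each list and the lists without chromosome I. Over the alternatives counted for it, the density ratio of chromosome III stayed above 1, from 1.48 without its 3 densest bins to 2.55 among the 500 strongest peaks. That of X stayed below 1, from 0.619 to 0.788, and at 0.788 among the 500 strongest peaks it did not pass the exact test (p = 0.067). Fewer peaks were tested there, and the autosomes in this ratio include III. Against I, II, IV and V, with 4.14 of those 500 peaks per Mb, X was close at 4.10. Not counted among the alternatives, combined peaks in no replicate had a ratio of 1.24 for III and 0.851 for X. Replicate 2 over 1 Mb bins, also not counted, had 0.605 for X. The share of combined peaks in both replicates was 43.0% with a 50% reciprocal overlap and 86.1% in the stronger part of the list. Covered length among the 1000 strongest peaks was 669.8 kb in the combined list, 565.2 kb in replicate 1 and 545.5 kb in replicate 2, as fewer peaks entered. No paired analysis was possible because the lists give a q-value per peak and no values of the input libraries were analysed here. The planned promoter, motif, gene list and transgene alternatives were not run for want of annotation in build WS180. Sequencing depth is unknown, so weak peaks found in 1 list cannot be called absent from another.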

Other observations

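The tests of a single cluster on chromosome III, of the number format, of interval width, of the regions around the missing peaks and of the end of I were chosen after the results were seen. So were the comparison of ratios between I and II to V and the spacing and position values in the next paragraph. The tests of weak peaks on III and of bins along I were set before their results were seen.

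Neighbouring NFYA-1 peaks under 1000 bp apart were more frequent than random placement inside 1 Mb bins gave. In the combined list 565 neighbouring pairs were at least 200 and under 1000 bp apart, against 234.9 ± 14.8 (SD over 1000 draws) when peaks were placed at random inside their own 1 Mb bin. The ratio was 2.41, and it was 2.43 in replicate 1 and 2.22 in replicate 2. No list held a gap under 200 bp, so closer peaks may have been merged by the caller, which was not tested. The count covers only pairs at or above that gap. Random placement inside a bin cannot tell whether the members of a pair are separate binding sites. In 137 of the 565 pairs both members were found in both replicates, and in 300 at least 1 member was in neither. The median −log10 q was 15.2 for the stronger and 5.38 for the weaker member. Along the chromosomes, the middle of 3 equal parts of the span of I held 39.0% of its combined peaks and that of II 38.0% (exact binomial against 33.3%, adjusted p = 0.00548 and 0.0426 over 18 tests of 6 chromosomes in 3 lists). By the same exact test it was 38.8% on I in replicate 1 (adjusted p = 0.0644) and 38.9% in replicate 2 (adjusted p = 0.0495). On II it was 35.2% in replicate 1 (exact test, adjusted p = 0.527) and 36.9% in replicate 2 (adjusted p = 0.181), so the call for II rests on the combined list. X held 31.7% of its peaks in the middle part (exact test, adjusted p = 0.527).

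The excess of peaks on chromosome III is the first pattern a biologist might follow up. A local cluster, as extra transgene copies at 1 locus would give, was argued against: without its 3 densest 1 Mb bins the density of III was still 1.48 times that of the other autosomes (permutation of bins, p = 2e-05). Extra weak peaks let in on III were argued against too, since III held 29.0% of the 500 strongest combined peaks (exact interval 25.06 to 33.19) on 13.8% of the span. Among those 500, 11 of 13 bins of III lay above the mean of the other autosomes, and without any count of reads a scaling of III that raised all its q values in each list stays open. A denser set of bound promoters on III is a biological hypothesis that stays untested. Neither gene positions in build WS180 nor the share of genes on each chromosome were used here.

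On chromosome I the combined q values were stronger, relative to those of the replicates, than on II to V. Stronger NFYA-1 binding on I would raise the replicate values alike, but the ratio that could show this also defines the pattern, so it was no separate test. At the same peaks the median ratio of combined to summed replicate −log10 q was 0.144 higher on I than on II to V. The difference was 0.198, 0.175 and 0.102 in the weakest, middle and strongest of 3 equal groups of peaks. All 15 bins of I (100%) lay above the median of II to V, as a step that acted on the whole chromosome when the combined list was made would give, but 16 of 17 bins of X (94.1%) did as well. No such step was itself tested, so whether there was one stays open.

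For the strong replicate regions that the combined list lacks, removal of wide intervals was argued against by 109 combined intervals at least as wide as the narrowest of the 4. Exclusion of more than 1000 bp on both sides was argued against on II and III, where a combined interval lay 294 and 776 bp away. These distances do not bear on a narrower exclusion or on one at 1 side only. On IV the nearest combined interval lay 15834 bp away. The gap around that region spans at least this distance on both sides, so it is wider than the 75th percentile of gaps between combined intervals (23775 bp). Its full width was not set against the 95th percentile (65708 bp), so exclusion on IV was not decided. Combined q values too small for the number format were not decided. At the median ratio of the 15 kept peaks with a summed replicate −log10 q of at least 200, the 4 would have a combined −log10 q of 286.9 to 453.3. The lowest ratio puts all 4 under the limit of 323.3, at 201.7 to 318.6. The highest puts the weakest, on I, at 319.8, also under it. With the floor at 150 the highest of 22 ratios puts it at 387.9, and 4 of the 22 pass the limit. Those 4 ratios come from peaks with sums under 200, against 371.4 for the region on I. The 1 kept peak with a larger sum than that, on III from 1618209, had a combined −log10 q of 232.8. No kept peak reached the sums of the regions on II, III and IV, so the number format stays undecided. The limit first used was about the same and, with the floor of 200, argued against this explanation; a limit of 307.7 tried next was dropped because a replicate 1 q of 6.57e-310 lies past it, and the floor of 150 was added last. The region on I could also have been lost with the right end of that chromosome, which cannot be told apart because 0 other replicate peaks lie beyond its last combined interval at 14971993. That interval lay 92002 bp from the region, farther than the 95th percentile of gaps. Rows lost after the lists were made were not tested.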
